A study of Homo sapiens with 22 samples.

How the data were processed

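The deposited data cover 22 libraries of small RNA from HEK293T cells in 10 groups, each made from 1 µg of RNA per the labels. RNA of wild-type cells was left untreated (WT_NT), treated with bisulfite (WT_BS) or treated with picoborane (WT_PB), with 2 libraries each. RNA of cells with a knockout of PUS1 (PUS1KO_BS, 3 libraries), TRUB1 (TRUB1KO_BS, 2) or PUS7 (PUS7KO_BS, 3), which encode pseudouridine synthases, was profiled after bisulfite. Polysome and input RNA of wild-type cells were profiled untreated (Polysome_NT, Input_NT) and after bisulfite (Polysome_BS, Input_BS), with 2 libraries each. Per the labels, bisulfite treatment used 2.4 M sodium sulfite with 0.36 M sodium bisulfite for 3 h at 70 °C and 60 min of desulphonation. Picoborane, taken from a 5 M stock, was also applied for 3 h at 70 °C. Cells for polysome and input RNA received cycloheximide at 100 µg/ml for 7 min.

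For each library the authors provided read counts per reference RNA, and these counts are raw and not scaled. They also deposited, for each position of each reference, counts of reads covering it (the pileup), of each base, of deletions and of insertions. The pileup is the sum of the base, deletion and insertion counts. The authors' mismatch fraction per position is the number of reads with a base other than the reference divided by the pileup. It was recomputed from the base counts at every position and matched. A score deposited for reverse-transcription stops is the relative change of the pileup between neighbouring positions, and it was not used. Per the submitters' processing notes, the builds hg38 and GRCh38 and the tool SAMtools were used, without versions. The aligner, the read filters and the way near-identical isodecoders shared reads are not given in the sources used here.

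The 294 references comprise 261 cytosolic tRNA isodecoders, 22 mitochondrial tRNAs, 2 ribosomal RNAs, 5 small nuclear RNAs and 4 Y RNAs, with 23095 positions. Library totals ran from 542690 to 12500087 reads. At the minimum coverage of 100 reads, a fraction of 50% has a 95% Wilson interval from 40.4% to 59.6%, and a count of 0 allows up to 3%. At 1000 reads the interval is 46.9% to 53.1%. Such limits cover counting error only, since the reads are not independent molecules. Coverage at the tRNA sites named for deletions or mismatches in wild-type and knockout libraries ran from 101 to 188876 reads. Some sites named outside tRNAs had less than 100 reads in a knockout library and were not tested there. Canonical tRNA positions were assigned from the reference sequences, by placing the named anticodon at 34 to 36 and the T-loop motif at 53 to 58. Where the motif was absent, the T arm was counted back from the CCA end, which takes its length as standard. This applies to most mitochondrial tRNAs, the initiator tRNAs and some other cytosolic tRNAs. Their T-arm positions are less certain, since mitochondrial T arms can differ in length. A site is written with the base and the position counted from the 5' end of its reference, with the canonical position given where it differs. T stands for uridine. Genome locations are those of RefSeq genes on GRCh38.p14, matched for 270 of 283 tRNA references.

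Deletion and mismatch fractions were tested with limma 3.58.1 in R 4.3.3 on the log2 ratio of reads with the event to reads without it, after adding 0.5 to each. Moderated statistics used eBayes with a trend and robust estimation. Sites needed a coverage of 100 reads in every library of a fit. A site was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested sites with a change in the mean fraction of at least 5 percentage points. Wild-type libraries shared a fit, as did the knockout libraries, the knockout libraries with WT_BS, and the polysome and input libraries. Every p is 2-sided. Abundance was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) at an adjusted p below 0.05. Printed abundances are TMM-scaled counts per 1e6 (CPM), whose sum can exceed 1e6. Each knockout was set against WT_BS and against the other knockouts. The labels put WT_NT, WT_BS and WT_PB in batch 1, the knockouts in batch 2 and the polysome and input libraries in batch 3, so that the comparison with WT_BS also crosses batches. A site that fell in both comparisons is called enzyme-dependent here.

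Lists of sites were fixed by base and canonical position. For pseudouridine these were T27 and T28 (PUS1 class), T54 and T55 (TRUB1 class), T13 and Tyr T35 (PUS7 class), T38 and T39 (PUS3 class), T31 and T32, D-loop T16 to T20b with T20 and T20a, T65 to T72, and T27, T28, T54 and T55 of mitochondrial tRNAs. For other bases they were A58, G26, A34, C32 of Ser, Thr and Arg tRNAs, C12 of Ser and Leu tRNAs and of other tRNAs, C48 to C50, G34 of the queuosine families, G46, and purines at 9 and 37. References were also listed by kind, amino acid, first anticodon base, the queuosine families and the families with a long variable arm. Lists were tested with fry of limma, adjusted over all lists and comparisons. Its directional p asks whether the members move, on balance, one way, and it does not compare a list with other sites. Sites and tRNAs are named by rule: called items ranked by absolute change, with the deepest isodecoder for each anticodon and position, named from the first 25. For each list the 2 largest that passed and the 2 deepest could be added. Items outside that rule are said to be chosen after their values were seen.

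These groups, comparisons, lists, tests and naming rule were chosen before the data were examined, together with these alternatives: a coverage minimum of 1000 reads, edgeR on event counts, the replicate number as a block, leaving out each library, summing isodecoders, summing runs of identical bases, another batch as control, size factors and the Wald test of DESeq2 1.42.0, no count filter, cytosolic tRNAs alone and both treatments in a joint fit. Chosen after seeing the data were re-matching of pileup tables, the untreated polysome and input libraries alone, knockout fits without the TRUB1KO libraries, and changes centred per base. Recovery was tested on simulated data with real means and spread. With 100 sites shifted by 10 points, limma recovered 40 in WT_BS against WT_NT, 88 in PUS1KO_BS against the other knockouts and 39 in Polysome_BS against Input_BS. With 25 points it recovered 79, 100 and 88, with at most 2 false calls. In the same order edgeR on event counts recovered 0, 24 and 0 of the smaller shifts and 9, 95 and 0 of the larger ones. The Polysome_BS simulation took coverage and spread from the pileup tables as labelled, some of which match the counts of another library. It therefore does not describe the re-matched data. edgeR recovered 29 of 30 references changed 2-fold in Polysome_NT against Input_NT. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and intervals came from scipy 1.17.1. Reads were not available, so that combinations of modifications on single reads were not analysed here.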

Results

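The series asks how modifications of human tRNA are read by sequencing and how they depend on each other, in HEK293T, an established embryonic kidney line. In MSR-seq, a multiplexed small-RNA sequencing method, many modified bases leave a mismatch or a deletion in the read. Bisulfite converts pseudouridine into an adduct read mostly as a deletion, and picoborane reduces acetylated and formylated cytidine, which is then read as T. Cytosolic tRNA took 85.0% ± 0.117 (SD, n = 2) of counts in WT_NT, 75.96% ± 0.0276 (n = 2) in WT_BS and 81.3% ± 0.191 (n = 2) in WT_PB. It took 73.05% ± 1.30 (n = 3) in PUS1KO_BS and 73.3% ± 1.69 (n = 3) in PUS7KO_BS, but 49.1% ± 8.94 (n = 2) in TRUB1KO_BS. In Polysome_NT and Polysome_BS, ribosomal 5S and 5.8S RNA held 47.5% ± 0.448 (n = 2) and 68.9% ± 0.315 (n = 2), against 5.15% ± 0.0987 (n = 2) and 13.7% ± 0.198 (n = 2) in the matching input libraries.

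Total counts per library were 1702151 to 1757221 in WT_NT, 1143846 to 1193867 in WT_BS and 1642976 to 1805462 in WT_PB. They were 826795 to 2062109 in PUS1KO_BS, 542690 to 1002393 in TRUB1KO_BS and 756151 to 2419417 in PUS7KO_BS. Totals were 1382879 to 1468957 in Polysome_NT, 1732908 to 1743365 in Polysome_BS, 11502158 to 12500087 in Input_NT and 7483405 to 7878962 in Input_BS. The study's design text calls the replicates biological, and no label says that they were separate cultures. They are taken as separate samples by label only, so each p measures the spread between libraries, which may be technical in part.

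The pileup tables of 3 libraries matched the counts of another library. The pileup labelled Polysome_BS replicate 1 matched the counts of Polysome_BS replicate 2 (median deviation per reference 0.234%, against 9.89% for its own counts). That labelled Polysome_BS replicate 2 matched Input_BS replicate 2 (0.139%, against 1471%), and that labelled Input_BS replicate 2 matched Polysome_BS replicate 1 (0.214%, against 94.0%). The other 19 pileups matched their own counts best, with deviations up to 1.12% and a next-best match no closer than 6.71%. Site fractions of bisulfite-treated polysome and input libraries are therefore given both as labelled and re-matched, an alternative chosen after seeing the data. Abundance uses the count tables, in which the ribosomal share and the depth of each library resemble those of its group partner.

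Bisulfite treatment of wild-type RNA marked the T-loop pseudouridine most strongly. In mt-tRNA-Asn-GTT, which decodes asparagine in mitochondria (MT 5657 to 5729), T54 was deleted in 91.4% ± 0.0752 (SD, n = 2) of WT_BS reads and in 0.172% ± 0.243 (n = 2) of WT_NT reads. In tRNA-Asp-GTC-2-1, T53 (canonical 54) went from 0.0580% ± 0.00507 (n = 2) to 88.8% ± 0.272 (n = 2; limma adjusted p 1.78e-05). TRUB1 modifies the base at 55, and in a run of identical bases a deletion can be placed at a neighbour, so T54 and T55 are read as 1 class. T67 (canonical 54) of the selenocysteine tRNA-SeC-TCA-1-1 reached 88.8% ± 0.463 (n = 2) and T53 (canonical 54) of tRNA-Trp-CCA-2-1 87.2% ± 0.187 (n = 2). In the anticodon stem, where PUS1 acts at 27 and 28, T27 of tRNA-Lys-CTT-2-1 (chromosome 1, 146039401 to 146039473) reached 80.2% ± 0.154 (n = 2). T36 (canonical 39) of mt-tRNA-Gly-TCC reached 85.9% ± 0.384 (n = 2). In the D stem, T13 of tRNA-Glu-CTC-1-1 (chromosome 1, 146035692 to 146035763) went from 0.446% ± 0.0243 (n = 2) to 80.2% ± 0.189 (n = 2). T50 of tRNA-Arg-ACG-2-1, in the T stem, reached 78.7% ± 1.40 (n = 2).

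Of 14974 sites tested between WT_BS and WT_NT, 1240 rose and 284 fell in deletion fraction. T made up 46.9% of the called sites and 23.3% of the tested ones. In the TRUB1 class 239 of 358 rose and 2 fell (240 and 2 adjusted over the list alone; median change 29.3 points, fry adjusted p 6.7e-07). In the PUS1 class 85 of 130 rose, in the PUS3 class 92 of 112 and in the PUS7 class 37 of 52, with the same counts adjusted over each list alone and none that fell. In mitochondrial tRNAs 18 of 21 T27 and T28 sites rose and 8 of 21 T54 and T55 sites. Deletions were not limited to T: 41 of 89 G26 sites rose and 9 fell, 48 of 172 purines at 37 rose, and 83 of 181 A58 sites fell while 14 rose. G38 (canonical 37) of tRNA-Leu-CAA-1-1, a purine position beside the anticodon, went from 0.333% ± 0.0360 (n = 2) to 71.2% ± 0.234 (n = 2). Of T31 and T32 sites 23 of 62 rose and 2 fell, and of D-loop T16 to T20b sites 30 of 277 rose and 15 fell, among which T20 and T20a gave 14 and 5 of 150. Of A34 sites 8 of 36 rose, of C32 sites of Ser, Thr and Arg tRNAs 15 of 42, of T65 to T72 sites 5 of 238, of C48 to C50 sites 7 of 335 and of G46 sites 1 of 109. At purine 9, 4 of 112 fell. None was called among 14 G34 sites of the queuosine families, or 18 and 19 C12 sites of Ser and Leu tRNAs and of other tRNAs.

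Bisulfite also changed mismatches, in both directions, and lowered those at most A58 sites, which hold N1-methyladenosine. A58 of tRNA-Arg-TCT-1-1, methylated by TRMT6 and TRMT61A, was mismatched in 85.3% ± 0.0139 (n = 2) of WT_NT reads and 1.71% ± 0.432 (n = 2) of WT_BS reads (limma adjusted p 7.19e-05). A58 of tRNA-Tyr-GTA-5-1 fell from 94.7% ± 0.0397 (n = 2) to 23.9% ± 2.69 (n = 2), and A56 (canonical 58) of tRNA-Gly-CCC-2-1 from 89.2% ± 0.956 (n = 2) to 18.0% ± 0.485 (n = 2). A9 of tRNA-Asp-GTC-2-1 fell from 83.6% ± 0.265 (n = 2) to 8.29% ± 0.236 (n = 2). T39 of tRNA-Arg-ACG-2-1 rose from 0.00275% ± 0.00388 (n = 2) to 59.6% ± 0.952 (n = 2). Of 14974 sites 340 rose and 399 fell, among them 161 of 181 A58 sites that fell and 3 that rose (162 and 4 adjusted over the list alone). Mismatches rose at 67 of 112 PUS3-class sites, 40 of 130 PUS1-class sites and 18 of 109 G46 sites, while 10 of 36 A34 sites, which hold inosine in A34 tRNAs, fell.

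Picoborane was used to read acetylcytidine and formylcytidine. C31 (canonical 34) of mt-tRNA-Met-CAT, the formylated wobble base of the mitochondrial methionine tRNA (MT 4402 to 4469), rose from 0.670% ± 0.0860 (SD, n = 2) mismatches in WT_NT to 81.1% ± 0.288 (n = 2) in WT_PB (limma adjusted p 1.53e-04). C12 of tRNA-Ser-AGA-1-1 (chromosome 6, 27541775 to 27541856), which NAT10 acetylates in Ser and Leu tRNAs, reached 53.3% ± 0.535 (n = 2). None of its 253 WT_NT reads had a mismatch, which allows up to 1.19%. C12 reached 50.9% ± 0.415 (n = 2) in tRNA-Ser-TGA-2-1 and 50.9% ± 1.01 (n = 2) in tRNA-Ser-GCT-3-1, and C35 (canonical 34) of tRNA-Leu-CAA-1-1, another site of formylation, 34.8% ± 1.96 (n = 2). All 18 C12 sites of Ser and Leu tRNAs rose (18 adjusted over the list alone; median 16.0 points, fry adjusted p 3.7e-05), and 0 of 19 C12 sites of other tRNAs did.

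Picoborane lowered mismatches at 4 named wobble uridines. T34 of tRNA-Glu-TTC-2-1, part of a 2-thiouridine derivative, fell from 36.6% ± 1.46 (n = 2) to 2.48% ± 0.00614 (n = 2), and T34 of tRNA-Gln-TTG-3-1 from 20.4% ± 0.472 (n = 2) to 0.864% ± 0.163 (n = 2). T31 (canonical 34) of mt-tRNA-Glu-TTC fell from 30.5% ± 0.589 (n = 2) to 3.60% ± 0.398 (n = 2) and T34 of mt-tRNA-Gln-TTG from 23.2% ± 1.82 (n = 2) to 1.44% ± 0.271 (n = 2). G26 of tRNA-Ser-AGA-1-1 rose from 10.2% ± 0.675 (n = 2) to 29.9% ± 0.115 (n = 2). G45 (canonical 46) of the initiator tRNA-iMet-CAT-1-1, a 7-methylguanosine position, rose from 0.577% ± 0.00508 (n = 2) to 13.8% ± 0.297 (n = 2), as did 19 of 109 G46 sites in all (22 adjusted over the list alone). Of 14974 sites 61 rose and 24 fell. With 2 libraries per arm, leaving out a WT_NT or WT_PB library leaves 1 in that arm, and the other groups then supply the spread. Fewer sites passed in such fits, which does not show that the result rests on a given library. Without either WT_PB library the C12 sites of tRNA-Ser-TGA-2-1 and tRNA-Ser-GCT-3-1, C35 of tRNA-Leu-CAA-1-1, G26 of tRNA-Ser-AGA-1-1 and T34 of tRNA-Gln-TTG-3-1 no longer passed, with changes of at least 19.4 points in size. T31 of mt-tRNA-Glu-TTC and T34 of mt-tRNA-Gln-TTG passed in none of the 4 fits that left out a library. Their changes there were -26.5 to -27.3 and -20.5 to -23.1 points.

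**Figure D1:**
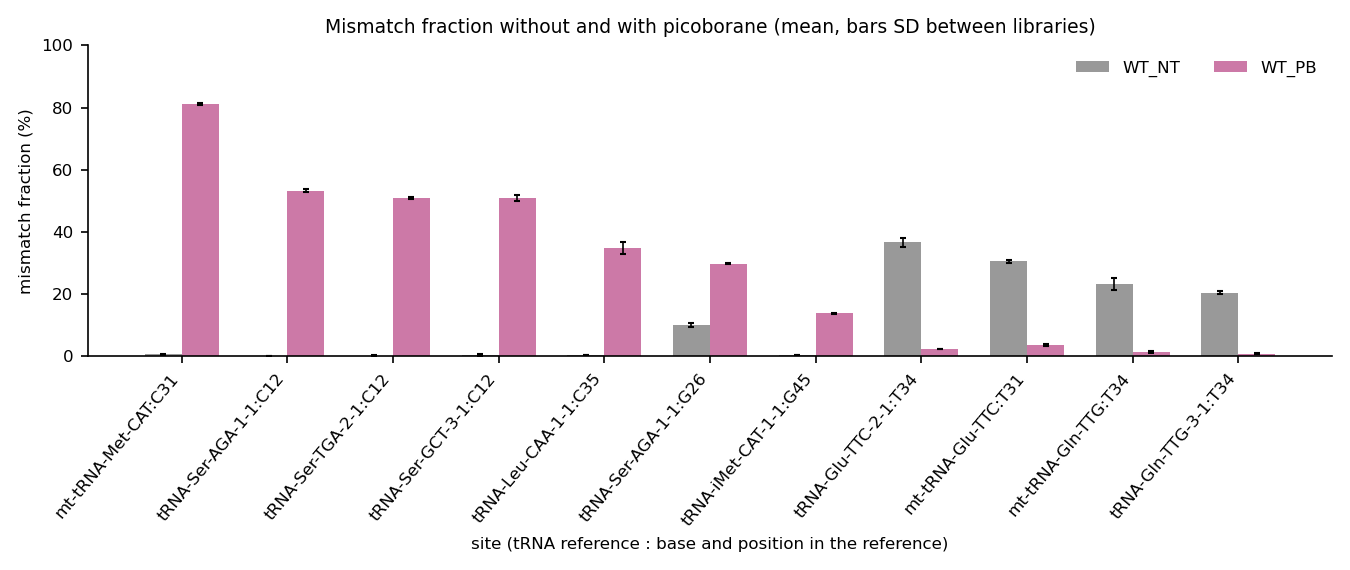
Mismatch fraction (%) at 11 named sites in WT_NT and WT_PB, as the mean of 2 libraries with the SD between them. C31 of mt-tRNA-Met-CAT went from 0.670% to 81.1%, and T34 of tRNA-Glu-TTC-2-1 from 36.6% to 2.48%.

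Deletions after picoborane served as a measure of what another chemical treatment leaves. T32 of tRNA-Glu-TTC-2-1, 2 bases before its modified wobble base, rose from 43.6% ± 0.170 (n = 2) in WT_NT to 67.7% ± 0.929 (n = 2) in WT_PB, and T33 from 35.5% ± 0.343 (n = 2) to 59.8% ± 0.702 (n = 2). T34 of tRNA-Glu-TTC-4-1 fell from 31.7% ± 0.154 (n = 2) to 6.32% ± 0.157 (n = 2). T28 (canonical 31) of mt-tRNA-Glu-TTC rose from 23.3% ± 0.0472 (n = 2) to 49.03% ± 0.726 (n = 2), and T32 of mt-tRNA-Gln-TTG from 28.8% ± 0.842 (n = 2) to 52.2% ± 1.63 (n = 2). Of 14974 sites 44 rose and 18 fell by limma, and none lay in the PUS1, TRUB1, PUS7 or PUS3 class. The same classes held 85, 239, 37 and 92 sites that rose after bisulfite. The count of 62 became 37 without WT_NT replicate 1 or without replicate 2, 33 without WT_PB replicate 1 and 28 without WT_PB replicate 2.

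The knockout libraries ask which deletions need each pseudouridine synthase. The mRNA of PUS1, TRUB1 and PUS7 was not measured, and the deletion signal at the class of each enzyme is what bears on the labels. At 63 PUS1-class sites of cytosolic tRNAs that rose with bisulfite in wild type, the median deletion fraction was 23.3% ± 0.314 (SD between libraries, n = 2) in WT_BS and 3.77% ± 0.176 (n = 3) in PUS1KO_BS. It was 14.9% ± 0.722 (n = 2) in TRUB1KO_BS and 14.8% ± 0.223 (n = 3) in PUS7KO_BS. At 206 TRUB1-class sites it was 69.0% ± 1.44 (n = 2) in WT_BS and 39.9% ± 3.30 (n = 2) in TRUB1KO_BS, against 62.4% ± 1.23 (n = 3) in PUS1KO_BS and 62.4% ± 1.65 (n = 3) in PUS7KO_BS. At 27 PUS7-class sites it was 22.1% ± 0.0678 (n = 2) in WT_BS and 0.575% ± 0.154 (n = 3) in PUS7KO_BS, against 19.4% ± 0.412 (n = 3) in PUS1KO_BS and 17.6% ± 1.17 (n = 2) in TRUB1KO_BS. At 73 PUS3-class sites, whose enzyme PUS3 was not a target, WT_BS had 26.6% ± 1.68 (n = 2) and the knockouts 13.8% ± 0.721 (n = 3), 12.0% ± 0.645 (n = 2) and 15.9% ± 0.608 (n = 3), for PUS1, TRUB1 and PUS7 in turn. Batch and genotype cannot be told apart against WT_BS, so each knockout was also set against the others of its batch.

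**Figure D2:**
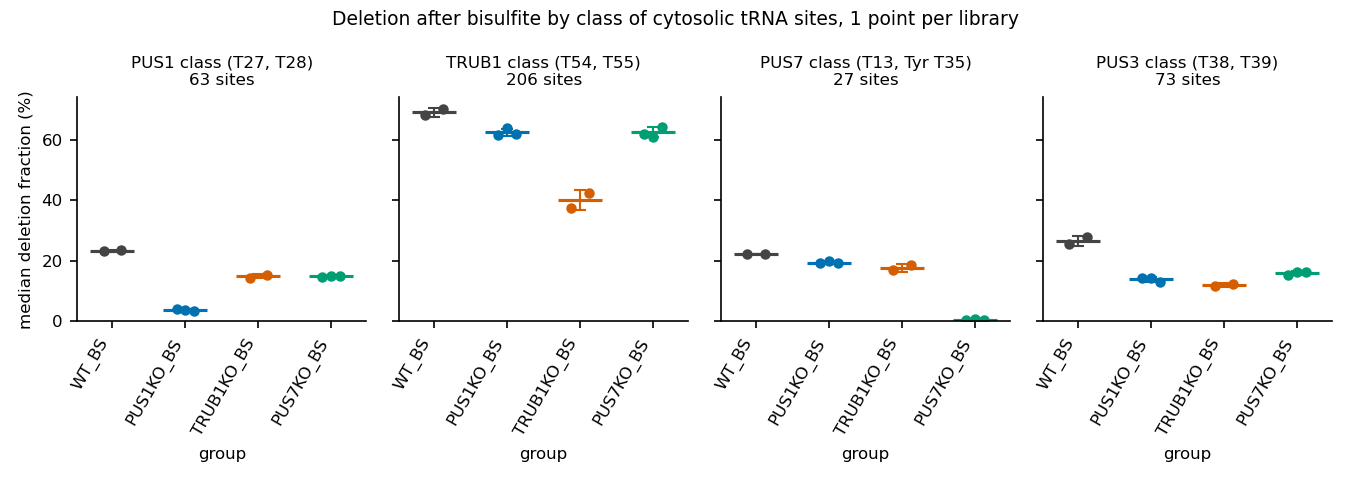
Median deletion fraction (%) after bisulfite per library, for 4 classes of cytosolic tRNA sites that rose with bisulfite in wild type, with lines and bars for the group mean and SD. Each knockout has the lowest value of the 4 groups in the class of its own enzyme, and at PUS3-class sites all 3 knockouts lie below WT_BS.

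Loss of PUS1 lowered deletions at positions 27 and 28 of mitochondrial and cytosolic tRNAs. T29 (canonical 27) of mt-tRNA-Leu-TAA (MT 3230 to 3304) was deleted in 7.42% ± 1.13 (SD, n = 3) of PUS1KO_BS reads, against 89.1% ± 1.89 (n = 2) in WT_BS, 83.7% ± 4.76 (n = 2) in TRUB1KO_BS and 76.3% ± 7.13 (n = 3) in PUS7KO_BS. T22 (canonical 27) of mt-tRNA-Lys-TTT fell to 4.09% ± 1.26 (n = 3), against 81.3% ± 1.39 (n = 2), 69.8% ± 2.68 (n = 2) and 61.8% ± 2.32 (n = 3) in the same order. T26 of mt-tRNA-Leu-TAG, T24 of mt-tRNA-Asp-GTC and T24 of mt-tRNA-His-GTG, all at canonical 27, fell to 2.60% ± 0.750 (n = 3), 4.26% ± 1.28 (n = 3) and 2.88% ± 0.614 (n = 3), from 68.7% ± 4.76 (n = 2), 70.3% ± 5.14 (n = 2) and 68.8% ± 2.04 (n = 2) in WT_BS. In cytosolic tRNA-Lys-CTT-2-1, T27 kept 22.8% ± 0.864 (n = 3), against 80.2% ± 0.154 (n = 2) in WT_BS, 56.7% ± 4.99 (n = 2) in TRUB1KO_BS and 65.4% ± 2.60 (n = 3) in PUS7KO_BS. T30 (canonical 31) of mt-tRNA-Leu-TAG rose to 37.4% ± 2.90 (n = 3), from 1.84% ± 0.311 (n = 2) in WT_BS and 4.26% ± 1.05 (n = 2) and 4.11% ± 0.893 (n = 3) in the other knockouts.

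Against WT_BS 654 of 12473 sites fell and 76 rose in PUS1KO_BS, and against the other knockouts 127 of 12536 fell and 172 rose. The 2 comparisons share the PUS1KO_BS libraries. Of the sites that fell, 106 did so in both, where independent lists share 6.61 and 20 simulations without an effect gave a mean of 0. Neither is a baseline for the overlap, since such simulations give few calls in either list and the 2 comparisons share libraries. Nothing is concluded from them. These 106 lie in 63 references, and 68 are T. In cytosolic tRNAs, 32 were T27, 11 were T28 and 10 were G26. The PUS1 class had 59 of 102 sites that fell against WT_BS and 45 of 105 against the other knockouts (59 and 45 adjusted over the list alone; fry adjusted p 5.8e-07 and 7.2e-06), and mitochondrial T27 and T28 had 17 of 20 and 15 of 20. Against WT_BS 114 of 313 TRUB1-class and 27 of 90 PUS3-class sites fell as well, while against the other knockouts 1 of each class did.

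Loss of TRUB1 lowered T-loop deletions to very different extents. T54 of mt-tRNA-Asn-GTT fell to 3.97% ± 1.16 (SD, n = 2) in TRUB1KO_BS, against 91.4% ± 0.0752 (n = 2) in WT_BS, 88.2% ± 0.934 (n = 3) in PUS1KO_BS and 88.0% ± 1.92 (n = 3) in PUS7KO_BS. T56 (canonical 54) of mt-tRNA-Leu-TAA fell to 10.0% ± 1.10 (n = 2) from 90.6% ± 0.654 (n = 2) in WT_BS. T53 (canonical 54) of mt-tRNA-Gln-TTG fell to 0.547% ± 0.0719 (n = 2), and T50 fell to 1.09% ± 0.242 (n = 2) in mt-tRNA-Ser-TGA (canonical 54), 0.397% ± 0.0805 (n = 2) in mt-tRNA-Glu-TTC (canonical 54) and 0.157% ± 0.0144 (n = 2) in mt-tRNA-Pro-TGG (canonical 55). Their WT_BS values were 70.0% ± 3.29, 74.04% ± 1.20, 51.3% ± 2.96 and 42.5% ± 5.68 (n = 2 each). Among cytosolic tRNAs, T53 (canonical 54) of tRNA-Glu-TTC-2-1 fell to 8.40% ± 0.996 (n = 2) from 73.1% ± 1.05 (n = 2) in WT_BS. T55 (canonical 54) of tRNA-Thr-AGT-1-1 fell to 21.8% ± 3.14 (n = 2) from 64.9% ± 1.31 (n = 2) and T54 of tRNA-Lys-TTT-3-1 to 20.2% ± 0.397 (n = 2) from 58.9% ± 1.67 (n = 2). T53 (canonical 54) of tRNA-Glu-CTC-1-1 kept 48.3% ± 0.658 (n = 2) of reads with a deletion, against 79.5% ± 0.101 (n = 2) in WT_BS and 75.6% ± 0.538 (n = 3) in PUS1KO_BS.

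In TRUB1KO_BS 712 sites fell and 57 rose against WT_BS, and 232 fell and 117 rose against the other knockouts. In both comparisons 185 sites of 140 references fell. Independent lists share 13.2 and simulations without an effect gave 0.1 on average and 1 at most, which are no baseline here either. Of the 185, 168 are T, and 127 are T54 of cytosolic tRNAs. The TRUB1 class had 184 of 313 sites that fell against WT_BS and 135 of 313 against the other knockouts (184 and 137 adjusted over the list alone; fry adjusted p 8.9e-06 and 0.00013). Mitochondrial T54 and T55 had 8 of 21 in each. PUS3-class sites also fell against the other knockouts, 23 of 90, with 1 that rose.

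Loss of PUS7 removed deletions at T13 and at several sites outside its class. T13 of tRNA-Glu-TTC-4-1 fell to 1.07% ± 0.653 (SD, n = 3) in PUS7KO_BS, against 79.9% ± 0.0636 (n = 2) in WT_BS, 77.3% ± 1.43 (n = 3) in PUS1KO_BS and 72.8% ± 0.634 (n = 2) in TRUB1KO_BS. T13 fell to 1.53% ± 0.827 (n = 3) in tRNA-Glu-CTC-1-1 and 0.668% ± 0.304 (n = 3) in tRNA-Pro-CGG-1-1, from 80.2% ± 0.189 (n = 2) and 64.9% ± 1.00 (n = 2). A T11 fell to 1.64% ± 0.737 (n = 3) in tRNA-His-GTG-1-1, 2.39% ± 0.520 (n = 3) in tRNA-Gly-TCC-2-1 and 0.599% ± 0.331 (n = 3) in tRNA-Asp-GTC-2-1, from 75.2% ± 0.780, 63.6% ± 0.139 and 58.1% ± 0.668 (n = 2 each) in WT_BS. A deletion is given where the alignment placed it. Whether those at T11 come from T11 itself or from T13 was not tested. T50 of tRNA-Arg-CCT-4-1 fell to 0.633% ± 0.142 (n = 3) from 35.7% ± 3.18 (n = 2), and T21 (canonical 20b) of tRNA-Leu-TAG-1-1 to 0.351% ± 0.339 (n = 3) from 58.01% ± 1.51 (n = 2). T50 of tRNA-Arg-ACG-2-1 fell to 0.293% ± 0.0964 (n = 3) from 78.7% ± 1.40 (n = 2) against WT_BS, while PUS1KO_BS and TRUB1KO_BS had 31.95% ± 1.18 (n = 3) and 28.5% ± 5.99 (n = 2). T39 of tRNA-Arg-TCT-1-1 rose to 63.9% ± 1.20 (n = 3), from 5.64% ± 2.85 (n = 2) in WT_BS and 13.2% ± 1.07 (n = 3) and 10.0% ± 2.08 (n = 2) in the other knockouts. C26 and G25 (canonical 25 and 24) of tRNA-Leu-CAG-1-1 rose to 56.6% ± 1.16 (n = 3) and 53.6% ± 0.571 (n = 3), from 11.2% ± 0.303 and 6.78% ± 1.07 (n = 2 each) in WT_BS.

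In PUS7KO_BS 639 sites fell and 65 rose against WT_BS, and 69 fell and 232 rose against the other knockouts. In both comparisons 60 sites of 36 references fell. Independent lists share 3.48 and simulations without an effect gave 0, which again are no baseline. Of the 60, 43 are T, with 23 T13 and 11 T11 of cytosolic tRNAs. The PUS7 class had 27 of 40 sites that fell against WT_BS and 24 of 41 against the other knockouts (27 and 24 adjusted over the list alone; fry adjusted p 1.5e-05 and 3.3e-05). Rises against the other knockouts lay largely in the classes that those lines had lost, with 94 of 313 TRUB1-class and 37 of 105 PUS1-class sites.

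**Figure D3:**
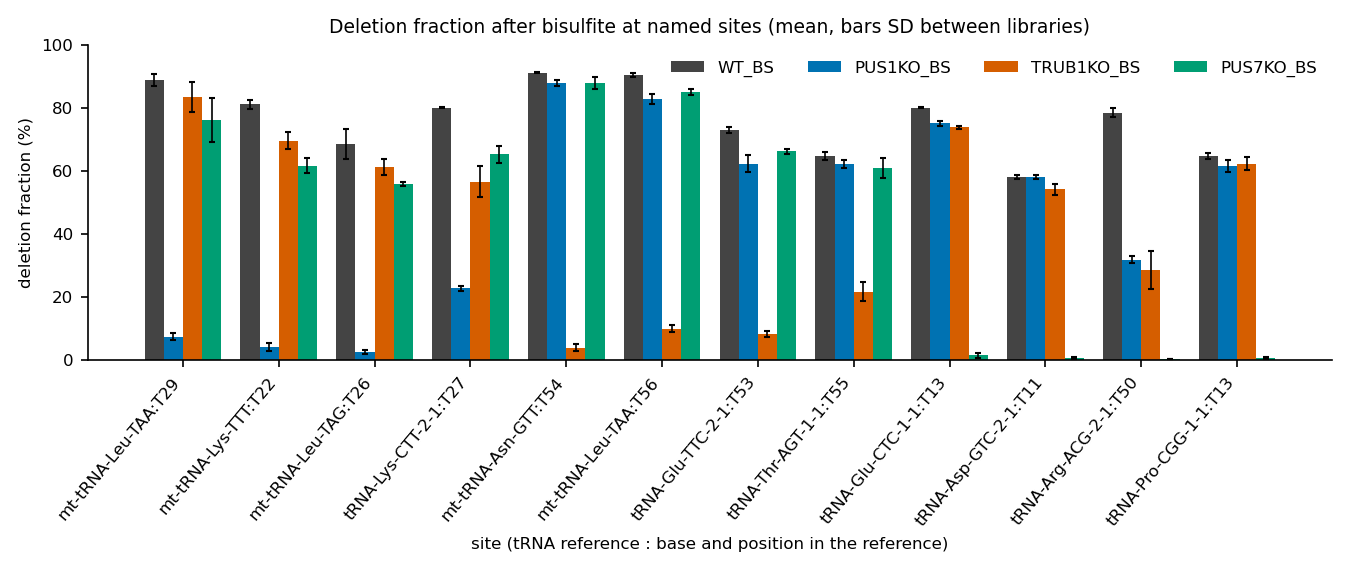
Deletion fraction (%) after bisulfite at 12 named sites in WT_BS and the 3 knockouts, as group means with the SD between libraries. The first 4 sites are lowest in PUS1KO_BS, the next 4 in TRUB1KO_BS and the last 4 in PUS7KO_BS.

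The count of calls against WT_BS differed with centring and with the control, and another control is also another batch. When each change was taken relative to the median change of the same base, an alternative chosen after seeing the data, the calls went from 730 to 351 in PUS1KO_BS, from 769 to 478 in TRUB1KO_BS and from 704 to 282 in PUS7KO_BS. With Input_BS as labelled for the control, PUS1KO_BS had 479 calls (203 rose, 276 fell) and TRUB1KO_BS 417 (121 rose, 296 fell), but 1 of the 2 pileups under that label matches a polysome library. Re-matched, PUS1KO_BS had 605 calls (226 rose, 379 fell), TRUB1KO_BS 589 (161 rose, 428 fell) and PUS7KO_BS 588 (232 rose, 356 fell). Near-identical isodecoders share a site: summed by anticodon and position, the calls against the other knockouts numbered 116, 122 and 108 of 3686 for PUS1, TRUB1 and PUS7.

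Mismatches were compared within the knockout batch at all bases, the targets of the enzymes included. In PUS1KO_BS the dimethylguanosine position 26, beside the lost pseudouridine, was read as a mismatch more often. The pileup includes reads with a deletion, and some G26 sites lost deletions in PUS1KO_BS. A rise of the mismatch fraction there was not separated from that loss. G26 of tRNA-Ser-CGA-4-1 had 81.3% ± 0.608 (SD, n = 3), against 42.9% ± 3.78 (n = 2) in TRUB1KO_BS and 42.6% ± 0.599 (n = 3) in PUS7KO_BS (limma adjusted p 2.14e-06). G26 of tRNA-Leu-TAA-1-1 had 83.2% ± 1.45 (n = 3), against 59.1% ± 5.07 (n = 2) and 63.9% ± 1.50 (n = 3). G27 (canonical 26) had 52.9% ± 0.266 (n = 3) in tRNA-Ile-AAT-5-1 and 40.2% ± 0.550 (n = 3) in tRNA-Asn-GTT-2-1, against at most 34.96% ± 0.980 (n = 3) and 25.5% ± 1.47 (n = 3) in the other knockouts. Against WT_BS the difference at that site of tRNA-Asn-GTT-2-1 was -2.59 points and did not pass. T27 of tRNA-Lys-CTT-1-1 fell to 11.9% ± 0.571 (n = 3), against 26.8% ± 0.939 (n = 2) and 28.6% ± 0.262 (n = 3). Of 12536 sites 41 rose and 42 fell. G26 sites rose in 22 of 64 (23 adjusted over the list alone; fry adjusted p 1.5e-05), and A58 sites fell in 14 of 158 (20 adjusted over the list alone). TRUB1KO_BS, with changes of the opposite sign at both lists, is among the controls.

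In TRUB1KO_BS A57 (canonical 58) of tRNA-Glu-CTC-1-1 had 30.3% ± 0.527 (SD, n = 2) mismatches, against 14.7% ± 0.408 (n = 3) in PUS1KO_BS and 21.8% ± 0.239 (n = 3) in PUS7KO_BS (limma adjusted p 6.77e-04). A59 (canonical 58) of tRNA-Thr-AGT-1-1 had 32.7% ± 2.45 (n = 2), against 17.2% ± 1.15 (n = 3) and 17.9% ± 3.42 (n = 3). That site no longer passed without TRUB1KO_BS replicate 1 (13.4 points) or with the replicate number as a block (15.1 points). Against WT_BS it was -3.74 points and did not pass. T51 (canonical 56) of mt-tRNA-Pro-TGG fell to 0.186% ± 0.0480 (n = 2), against 19.5% ± 1.21 (n = 3) and 17.9% ± 1.13 (n = 3), and G26 of tRNA-Met-CAT-1-1 fell to 35.5% ± 3.79 (n = 2), against 56.96% ± 2.13 (n = 3) and 60.5% ± 1.05 (n = 3). Of 12536 sites 38 rose and 36 fell. A58 sites rose in 22 of 158 (39 adjusted over the list alone), and G26 sites fell in 12 of 64 (14 adjusted over the list alone). PUS1KO_BS, where G26 mismatches rose and A58 mismatches fell, is among the controls, so these counts are not separated from its own changes. Bisulfite alone lowered A58 mismatches in wild type, and PUS3-class deletions were lower in TRUB1KO_BS as well (23 of 90 fell), so the rise at A58 is not separated here from the strength of the reaction. The count of 74 became 22 without TRUB1KO_BS replicate 1, 48 without PUS7KO_BS replicate 1 and 41 by edgeR.

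In PUS7KO_BS A9 of tRNA-Asp-GTC-2-1, a methylated purine near the lost pseudouridine, had 36.5% ± 0.670 (SD, n = 3) mismatches, against 10.1% ± 0.299 (n = 3) in PUS1KO_BS and 11.2% ± 0.427 (n = 2) in TRUB1KO_BS (limma adjusted p 3.01e-06). G6 of the same tRNA had 61.2% ± 0.510 (n = 3), against 42.5% ± 0.137 (n = 3) and 44.6% ± 0.364 (n = 2). G6 of tRNA-Gly-TCC-2-1 fell to 6.57% ± 0.422 (n = 3), against 25.96% ± 1.17 (n = 3) and 20.1% ± 1.47 (n = 2), and G9 of tRNA-Pro-TGG-3-1 to 0.989% ± 0.135 (n = 3), against 9.45% ± 0.365 (n = 3) and 11.2% ± 0.140 (n = 2). A57 (canonical 58) of tRNA-Pro-CGG-1-1 had 18.2% ± 1.03 (n = 3), against 8.06% ± 0.501 (n = 3) and 9.57% ± 0.636 (n = 2), a rise that did not pass against WT_BS (4.27 points). Of 12536 sites 30 rose and 29 fell, and 109 were called without the TRUB1KO libraries, an alternative chosen after seeing the data. With WT_BS as control the calls numbered 364, 342 and 353 in PUS1KO_BS, TRUB1KO_BS and PUS7KO_BS, across batches.

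The polysome libraries ask whether tRNAs bound to ribosomes are modified differently from input tRNA. As labelled, 0 of 11090 sites were called by limma in each of 3 tests. For mismatches in untreated libraries 1130 sites had an unadjusted p below 0.05 and edgeR called 1. For mismatches after bisulfite 237 did and edgeR called 0, and for deletions after bisulfite 121 did and edgeR called 0. The 0 of edgeR says little, since it recovered 0 of 100 simulated shifts of 25 points in that last comparison. That simulation used the spread of the pileups as labelled, which mix the groups, so it gives no recovery for the re-matched data. Re-matched, 111 deletion sites were called after bisulfite, of which 87 fell and 24 rose. T54 of tRNA-Met-CAT-1-1 then had 41.2% ± 5.19 (SD, n = 2) in Polysome_BS and 69.5% ± 0.228 (n = 2) in Input_BS (limma adjusted p 6.1e-04). T54 of tRNA-Arg-TCT-1-1 had 26.9% ± 5.35 (n = 2) against 53.8% ± 1.58 (n = 2), and T54 of tRNA-Phe-GAA-1-1 41.5% ± 6.24 (n = 2) against 65.7% ± 2.88 (n = 2). TRUB1-class sites fell in 49 of 308 and rose in 2.

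Mismatches after bisulfite, re-matched, were called at 121 sites, of which 102 rose and 19 fell, and 79 of 157 A58 sites rose. A58 of tRNA-Met-CAT-1-1 had 49.7% ± 4.14 (SD, n = 2) in Polysome_BS and 26.1% ± 0.0509 (n = 2) in Input_BS, A58 of tRNA-Arg-TCT-1-1 44.2% ± 3.47 (n = 2) and 22.1% ± 0.841 (n = 2), and A58 of tRNA-Tyr-GTA-5-1 53.995% ± 4.25 (n = 2) and 34.9% ± 2.88 (n = 2). The untreated libraries matched their own counts, but share an estimate of the spread with the others. Their count went from 0 to 13 once the others were re-matched and to 16 when they were fitted alone, both chosen after seeing the data. C52 of tRNA-SeC-TCA-1-1, in its variable arm, had 24.1% ± 3.62 (n = 2) mismatches in Polysome_NT and 0.282% ± 0.0475 (n = 2) in Input_NT (re-matched adjusted p 7.9e-05). The wobble base T35 (canonical 34) of tRNA-Leu-TAG-1-1 had 62.3% ± 1.60 (n = 2) against 48.9% ± 0.709 (n = 2), and T34 of tRNA-Ser-TGA-2-1 34.2% ± 0.780 (n = 2) against 23.7% ± 0.232 (n = 2). Of the A58 sites in untreated libraries, 1 of 157 was called after re-matching.

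Abundance was compared between the polysome fraction and input. Ribosomal 5S and 5.8S RNA rose in Polysome_NT by 4.38 (SE 0.11) and 4.34 on the log2 scale (edgeR adjusted p 1.4e-18 for both) and in Polysome_BS by 3.65 and 3.85. The initiator tRNA-iMet-CAT-1-1, which starts translation, rose from 3211 ± 288 (SD, n = 2) to 13363 ± 410 (n = 2) CPM in untreated libraries, a log2 change of 2.06, and by 1.61 after bisulfite. The selenocysteine tRNA-SeC-TCA-1-1 (chromosome 19, 45478601 to 45478687), which decodes a recoded stop codon, fell from 1039 ± 37.2 (n = 2) to 185 ± 27.6 (n = 2), a log2 change of -2.49, and by -1.41 after bisulfite. Mitochondrial tRNAs, which serve ribosomes outside cytosolic polysomes, fell in 17 of 22 and rose in 2 in Polysome_NT, and fell in 18 and rose in 1 in Polysome_BS. mt-tRNA-Cys-GCA changed by -2.05 and -1.96 on the log2 scale, in untreated and bisulfite libraries, and mt-tRNA-Thr-TGT went from 298 ± 36.4 (n = 2) to 74.7 ± 12.5 (n = 2) CPM in the former and by -1.68 in the latter. mt-tRNA-Val-TAC, which is a structural part of the mitochondrial ribosome, rose by 1.88 and 1.44. tRNA-Glu-CTC-2-1 rose by 1.38 and 1.17, and the spliceosomal RNU5A-1 and RNU6-1 by 2.70 and 2.20 in untreated libraries and 1.64 and 1.71 after bisulfite.

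Of 285 references 100 rose and 85 fell in Polysome_NT, and 42 rose and 149 fell in Polysome_BS. The division into up and down depends on the scaling. With DESeq2 size factors it was 78 and 101 in untreated libraries and 77 and 106 after bisulfite, with cytosolic tRNAs alone 46 and 113, and 76 and 75, and with both treatments in a joint fit 58 and 110. The median log2 change over all references moved from 0.05 to -0.10 with DESeq2 size factors and -0.35 with cytosolic tRNAs alone in untreated libraries, and from -0.50 to -0.16 and -0.04 after bisulfite. Without Polysome_BS replicate 1 the bisulfite count fell from 191 to 127 (72 rose, 55 fell), with a median of -0.06. Mitochondrial tRNAs then fell in 12 of 22 and families with a long variable arm in 14 of 38. Families with a long variable arm (Ser, Leu and selenocysteine) fell in 21 of 37 and rose in 0 in Polysome_NT, and fell in 34 of 37 in Polysome_BS, with a negative median under each scaling. Elongator Met fell in 6 of 7, Trp in 5 of 5, Ile in 9 of 14 and Leu in 13 of 18 in Polysome_NT, also with negative medians under each scaling in both treatments. The queuosine families (Asn, Asp, His and Tyr) rose in 21 of 28 and fell in 2 in Polysome_NT, with a median of 0.87 that stayed positive under each scaling (0.73 and 0.45). After bisulfite 8 rose and 5 fell, or 17 and 3 with DESeq2 size factors. Tyr rose in 7 of 8 and Pro in 7 of 7 in Polysome_NT, Pro in 2 with cytosolic tRNAs alone.

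Other families differed in direction in Polysome_NT. Rises and falls were 13 and 7 of 28 for Ala, 10 and 4 of 20 for Arg, 10 and 1 of 16 for Asn, 3 and 0 of 3 for Asp, 1 and 3 of 20 for Cys, and 6 and 0 of 11 for Gln. They were 3 and 0 of 7 for Glu, 9 and 0 of 12 for Gly, 1 and 0 of 1 for His, 6 and 4 of 17 for Lys, and 3 and 0 of 4 for Phe. Ser had 0 and 7 of 18, Thr 8 and 1 of 16 and Val 3 and 5 of 17. With cytosolic tRNAs alone the medians of Ala, Arg, Glu, Lys and Thr turned negative, those of Glu and Lys also with DESeq2 size factors. By first anticodon base they were 19 and 16 of 51 for A, 31 and 18 of 70 for C, 29 and 5 of 64 for G and 13 and 28 of 67 for T, and the medians of A, C and G turned negative with cytosolic tRNAs alone, that of A also with DESeq2 size factors. Initiator Met rose in 2 of 2, small nuclear RNAs in 4 of 5, and Y RNAs fell in 1 of 4.

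**Figure D4:**
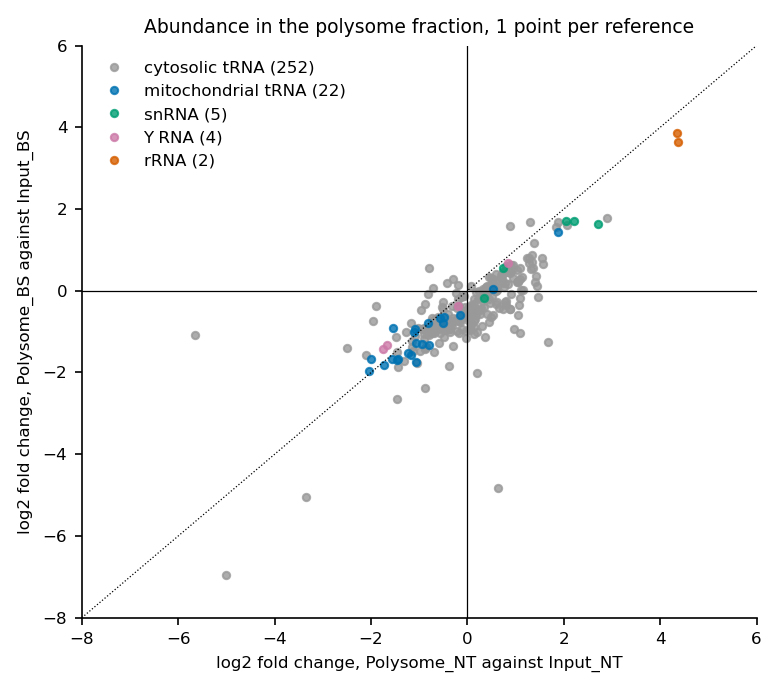
Log2 fold change of each of 285 references in polysome against input libraries, untreated on the x axis and after bisulfite on the y axis (2 libraries per group), coloured by kind, with a dotted line of equal change. The 2 ribosomal RNAs lie above 3 on both axes and most mitochondrial tRNAs lie below 0 on both.

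Abundance in the knockout libraries was compared within their batch, after bisulfite. No knockout library was left untreated, and bisulfite changed the recovery of tRNAs in wild type. Abundance therefore cannot be told apart here from recovery after the reaction. In TRUB1KO_BS all 22 mitochondrial tRNAs rose (median 1.92 on the log2 scale). mt-tRNA-Pro-TGG, whose T-loop deletions were lost there, had 10472 ± 3575 (SD, n = 2) CPM, against 478 ± 14.8 (n = 3) in PUS1KO_BS and 507 ± 41.5 (n = 3) in PUS7KO_BS, a log2 change of 4.41 (SE 0.15, edgeR adjusted p 2.96e-07). mt-tRNA-Ser-TGA rose by 3.70, mt-tRNA-Glu-TTC by 3.18 and mt-tRNA-Gln-TTG by 2.74, all with lost T-loop deletions as well. RNY1 rose by 2.29, RNU1-1 by 1.96 and 5.8S RNA by 1.70, as did all 5 small nuclear RNAs and all 4 Y RNAs, so that the rise was not limited to tRNAs that lost deletions. In PUS1KO_BS tRNA-Ala-AGC-10-1 rose by 2.34, to 703 ± 41.97 (n = 3) from 102 ± 8.17 (n = 2) and 192 ± 33.9 (n = 3). tRNA-SeC-TCA-1-1 rose by 1.14, which against WT_BS was -0.05 and did not pass, and mt-tRNA-Ser-TGA fell by 2.61, which against WT_BS was -0.31 and did not pass. In PUS7KO_BS tRNA-Val-CAC-4-1 fell by 1.25, tRNA-Phe-GAA-1-1 rose by 0.93 and 16 of 18 Ser tRNAs rose, while 1 fell. tRNA-Ile-GAT-1-1 rose by 1.08 and reversed to -1.09 against WT_BS. Of 273 references 70 rose and 69 fell in PUS1KO_BS, 91 and 86 in TRUB1KO_BS, and 79 and 80 in PUS7KO_BS. Mitochondrial tRNAs fell in 18 and 21 of 22 in PUS1KO_BS and PUS7KO_BS, comparisons that hold TRUB1KO_BS among the controls.

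Treatment changed which tRNAs were recovered. After bisulfite tRNA-Tyr-GTA-5-1 fell from 11585 ± 891 (SD, n = 2) to 935 ± 41.65 (n = 2) CPM, a log2 change of -3.63 (edgeR adjusted p 2.99e-07). tRNA-Arg-ACG-2-1 changed by -3.13, tRNA-Arg-TCT-1-1 by -3.12, tRNA-Ile-TAT-2-1 by -2.60 and tRNA-Met-CAT-1-1 by -2.49, while tRNA-Ser-CGA-4-1 rose by 1.92 and tRNA-Ala-AGC-8-1 by 1.85. Tyr and elongator Met fell in 8 of 8 and 7 of 7, Arg in 15 of 18 and Pro in 6 of 7, while Ser rose in 17 of 18. Of 276 references 124 rose and 101 fell, with a median log2 change of 0.18 that was 0.00 with DESeq2 size factors. After picoborane tRNA-Ile-AAT-7-1 changed by -1.27 and tRNA-Tyr-GTA-5-1 by -1.18, and mt-tRNA-Ile-GAT rose by 1.13. Ile fell in 13 of 14, Tyr in 8 of 8 and Met in 6 of 7, while Ser rose in 13 of 18. Of 276 references 74 rose and 80 fell, or 62 and 103 with DESeq2 size factors, which moved the median from 0.00 to -0.10.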

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

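The tests of mismatches near deletions, of mismatches with the targets included and of the splits of the knockout libraries were chosen before the result was seen, and the other tests below only after it.

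The ratio of polysome to input differed between untreated and bisulfite libraries for 104 of 285 references (edgeR interaction term, adjusted p below 0.05). It was higher untreated for 100 and lower for 4, with a median shift over all references of 0.43 on the log2 scale, and 101 of the 104 were cytosolic tRNAs. Count and direction depend on the scaling. With DESeq2 size factors 18 were called, 5 higher and 13 lower (median -0.061), and with cytosolic tRNAs alone 73, 1 higher and 72 lower (median -0.38). Without Polysome_NT replicate 1 or 2 the counts were 100 and 52, and without Polysome_BS replicate 1 or 2 they were 58 and 51, with at most 3 higher in each and negative medians. Without each of the 4 input libraries in turn they were 57 to 92, with 3 or 4 lower in each and medians of 0.41 to 0.47. No direction is read from the 104.

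Insertions were not part of the planned tests. Of 14974 sites, 22 changed with bisulfite in wild type (20 rose and 2 fell by limma), and 0 changed with picoborane, where 4991 had an unadjusted p below 0.05. T38 of tRNA-Ala-AGC-8-1 reached 17.3% ± 0.153 (n = 2) insertions, G19 of tRNA-Thr-AGT-1-1 10.6% and G23 (canonical 24) of tRNA-Trp-CCA-2-1 6.17%.

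Deletion fractions were lower in all 3 knockouts than in WT_BS at many sites, also outside the class of the lost enzyme. At T38 and T39, 8 of 8 knockout libraries had a median log2 odds of deletion below both WT_BS libraries, in line with a weaker bisulfite reaction in that batch or with another difference between batches. At the class of its own enzyme each of the 3 knockouts had the lowest median change of the 3, which a shift of the whole batch does not give. Outside tRNAs the mean was lower in all 3 knockouts at 29 of 36 sites that rose with bisulfite in wild type and higher in all 3 at 6, among them T52 of RNU5A-1 (9.12 points in PUS1KO_BS, adjusted p 0.00214; 4.31 and 2.23 points in TRUB1KO_BS and PUS7KO_BS, which did not pass). The T38 and T39 sites and the 36 outside tRNAs were chosen with the same WT_BS libraries, which favours lower values elsewhere. At the T sites among the 36 the knockout means stayed above WT_NT. At G78 of 5.8S RNA they lay below it (1.71%, 1.81% and 1.91% in PUS1KO_BS, TRUB1KO_BS and PUS7KO_BS, against 4.82%). They also lay below it at G35 of RNY5 (at most 1.54%, against 2.82%) and G46 of RNY4 (at most 2.435%, against 3.94%). At G42 of RNU2-1, with too little coverage in the knockouts to be tested, they were at most 3.29%, against 5.34%. A weaker reaction alone would not give such values. Sites that fell against WT_BS alone cannot be told from an effect of the batch.

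After re-matching, A58 mismatches were higher and T54 deletions lower in Polysome_BS than in Input_BS. Pileups of 3 of 22 libraries matched the counts of another library, which mixes the groups as labelled and fits the 0 calls found that way. A lower deletion fraction in Polysome_BS was seen at 94.97% (151 of 159) of the T13, T27, T28, T38 and T39 sites that rose with bisulfite in wild type, with a median of -2.98 points. That is in line with a weaker reaction in the polysome libraries, since bisulfite itself lowers A58 mismatches. In untreated libraries 53.5% (84 of 157) of the A58 sites had more mismatches on polysomes, with a median of 0.11 points. After bisulfite, re-matched, the median over the A58 sites was 6.50 points, a general shift of a size that the untreated libraries did not show. Whether polysome tRNA holds slightly more 1-methyladenosine, the share of 53.5% cannot tell.

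Mismatch fractions changed in the knockouts, at targets of the enzymes and at other bases. Of the called sites 65.7% (142 of 216) lay at or within 5 bases of a called deletion site of the same tRNA, against 18.8% to 23.9% of all tested sites. A different placement of reads around a changed deletion could produce some of them, and this value cannot tell which. The contrast is partly built in, since a called deletion site counts as near itself and the pileup includes reads with a deletion. References with an enzyme-dependent deletion site more often had a called mismatch (Fisher's exact test, odds ratios 4.12 for PUS1, 3.38 for TRUB1 and 4.51 for PUS7), but the calls include the targets themselves, so this is partly built in and decides nothing. Without the targets and the 5 bases on each side of each class position, the odds ratio was 1.16 for PUS1 (11 of 63 tRNAs against 19 of 123, adjusted p 0.833), 1.91 for TRUB1 (21 of 139 against 4 of 47, 0.490) and 3.21 for PUS7 (9 of 36 against 14 of 150, 0.0610). None of the 3 passed, so it stays open whether mismatches away from the targets follow the lost deletions.

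All 56 splits of the 8 knockout libraries into 3 and 5 were fitted as 2 groups. For PUS1KO_BS, 1 of 56 splits, the real one, reached its 130 deletion calls, 45 mismatch calls and 39 abundance calls. The next highest were 91, 34 and 22, all from the split that holds the PUS7KO_BS libraries apart. For PUS7KO_BS, 2 of 56 splits reached its 91, 34 and 22 calls, the real split and that of PUS1KO_BS. Every other split gave no call. A split that divides a knockout puts its difference into the spread, so few calls were bound to follow. The splits show only that libraries of a knockout resemble each other.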

How the results depend on the processing

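Of 260 counts under an alternative, 209 stayed within 1.5-fold of the result and 51 moved. Of the values of named items, 1471 kept their call or lack of one, 10 gained a call, 23 lost it and 4 reversed in sign. The size of the change was not compared. The cause was not tested except where given.

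The 4 that reversed did so with WT_BS of batch 1 as control in place of the other knockouts: mismatches at G27 (canonical 26) of tRNA-Asn-GTT-2-1 in PUS1KO_BS (-2.59 points, adjusted p 0.179), mismatches at A59 (canonical 58) of tRNA-Thr-AGT-1-1 in TRUB1KO_BS (-3.74 points, 0.419), abundance of tRNA-SeC-TCA-1-1 in PUS1KO_BS (-0.046 log2, 0.696) and abundance of tRNA-Ile-GAT-1-1 in PUS7KO_BS (-1.09 log2, 0.00043). The first 3 did not pass, so they are no evidence of an opposite change.

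A coverage minimum of 1000 reads tests fewer sites. Deletion calls became 754 for WT_BS and 33 for WT_PB against WT_NT, and mismatch calls 369 and 45. Against WT_BS, deletion calls became 161 (PUS1KO_BS), 171 (TRUB1KO_BS) and 148 (PUS7KO_BS). Against the other knockouts they became 56, 59 and 45, and mismatch calls 17, 18 and 6. Summed isodecoders are also fewer: deletion calls became 434 for WT_BS and 25 for WT_PB, 244, 248 and 249 for the knockouts against WT_BS, and 116, 122 and 108 against each other.

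The difference of the polysome to input ratio between treatments, 104 references, became 18 with DESeq2 size factors and 73 with cytosolic tRNAs alone, both mostly of the other sign, alternatives chosen after seeing the data.

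Leaving out each library in turn gave 28 to 37 deletion calls for WT_PB, 9 to 44 mismatch calls for WT_PB, 22 to 98 mismatch calls for TRUB1KO_BS and 127 to 174 abundance calls for Polysome_BS. In PUS1KO_BS and PUS7KO_BS, samples with the same replicate number were not closer to each other (correlation of deviations from -0.29 to -0.02). In wild type, abundance of same-number libraries deviated together across the 3 treatments (0.27 to 0.49), while deletion and mismatch sites hardly did (0.01 to 0.05). Abundance did so between Input_NT and Input_BS (0.52) and between Polysome_NT and Polysome_BS (0.18), and for polysome against input it was -0.11 untreated and 0.17 after bisulfite. The number may thus mark a shared RNA sample in some of these groups, which no label states and 2 numbers cannot decide. As a block it gave 43 mismatch calls for WT_PB and 31 for TRUB1KO_BS, where A59 of tRNA-Thr-AGT-1-1 (15.1 points) did not pass. edgeR gave 41 mismatch calls for TRUB1KO_BS and 1 for Polysome_NT.

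With Input_BS of batch 3 as labelled for the control, deletion calls were 479 for PUS1KO_BS and 417 for TRUB1KO_BS, and with re-matched pileups 605 and 589. Changes centred per base gave 351, 478 and 282 for PUS1, TRUB1 and PUS7. With WT_BS as control, mismatch calls were 364, 342 and 353. Without the TRUB1KO libraries PUS7KO_BS had 109.

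Re-matched pileups gave 13 mismatch calls for Polysome_NT, 121 for Polysome_BS (114 with the block) and 111 deletion calls for Polysome_BS (102 with the block). Untreated libraries alone gave 16. As labelled these were 0, since the tables of 3 libraries mix the groups.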

Other observations

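The test of Gln tRNAs was chosen before its result was seen, and the small nuclear and ribosomal RNA sites were picked after their values were seen.

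Bisulfite-induced deletions also occurred in small nuclear and 5.8S ribosomal RNA. T85 of RNU6-1 reached 70.6% ± 1.19 (SD, n = 2) in WT_BS, T40 66.1% ± 1.05 (n = 2) and T31 55.4% ± 1.06 (n = 2). T69 of 5.8S RNA reached 59.7% ± 0.251 (n = 2), T52 of RNU5A-1 53.8% ± 2.22 (n = 2), T53 of RNU2-1 49.2% ± 3.09 (n = 2) and T5 of RNU1-1 45.99% ± 0.140 (n = 2). In the knockouts T5 of RNU1-1 had 57.9% ± 0.237 (n = 3; PUS1KO_BS), 55.8% ± 4.12 (n = 2; TRUB1KO_BS) and 61.2% ± 3.52 (n = 3; PUS7KO_BS), a site with too little coverage to be tested there. In RNU2-1 10 of 188 sites rose, and in 5S RNA 0 of 121. Against the other knockouts, T53 and T58 of RNU2-1 fell in TRUB1KO_BS by 15.7 and 11.0 points (limma adjusted p 0.00355 and 0.000203). T9 of RNU6-1 rose in the same comparison by 13.1 points (limma adjusted p 0.00503). Against WT_BS its change was -8.52 points in TRUB1KO_BS, which did not pass, and -22.0 and -21.2 points in PUS1KO_BS and PUS7KO_BS, which did. The rise at T9 is thus relative to the other knockouts only.

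T13 of Gln tRNAs was read as an insertion after bisulfite. Over 7 such sites the mean was 35.6% ± 0.181 (SD, n = 2) in WT_BS and 0.0929% ± 0.0563 (n = 2) in WT_NT. It was 37.8% ± 0.0943 (n = 3) in PUS1KO_BS and 36.1% ± 1.34 (n = 2) in TRUB1KO_BS, but 1.47% ± 0.837 (n = 3) in PUS7KO_BS. These 7 sites were the only insertion sites of 12536 called in PUS7KO_BS against the other knockouts. The mean deletion fraction at the same sites was 6.92% ± 0.168 (n = 2) in WT_BS and 0.311% ± 0.165 (n = 3) in PUS7KO_BS. The value of 1.47% suggests that the insertions depend on PUS7, a hypothesis that rests on these libraries alone and that libraries with PUS7 restored would check.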
